A study of Mus musculus with 16 samples.

How the data were processed

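Polyadenylated RNA of thoracic aortas from mice was sequenced in 16 libraries, each from 1 animal as the labels list them. The animals carried floxed alleles of Yap1 and Wwtr1, the genes of the transcriptional coactivators YAP and TAZ, and were injected with tamoxifen. Those called KO also carried a tamoxifen-inducible Cre recombinase under the control of the smooth muscle gene Itga8, and those called control lacked Cre. The 4 groups of 4 libraries were KO and control at 2 weeks and at 8 weeks, counted from the first injection, per the design text of the series. Libraries were assigned to groups from the animal number, genotype, time and sex in the labels, never from values. Each group at 2 weeks held 2 females and 2 males, and each group at 8 weeks held 3 females and 1 male.

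Per the submitters' processing notes, reads of 150 bp were handled with HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 against the mouse build mm10. The raw fragment counts per gene used here were deposited by the authors in a table per time, each holding the 8 libraries of that time. The same tables held the authors' log2 fold changes, and these deposited log2 values were used only to compare calls. Likewise, the p-values and adjusted p-values deposited by the authors were read only for that comparison. The gene lengths deposited by the authors entered only a check of length bias. The 32 columns of size-factor scaled counts and FPKM values were not used here, since raw counts were at hand. The release of the gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. The deleted exons of Yap1 and Wwtr1, the time of day of sampling, and any batch of library preparation or sequencing are also not given in the sources used here.

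Gene identifiers were compared with the GENCODE M21 annotation of mm10. Of 28260 genes in the 2-week table, 28247 were found there, and of 29343 in the 8-week table, 29330 were found. The tables shared 26853 genes; 1407 were listed only at 2 weeks and 2490 only at 8 weeks, and those were left out of every fit that joined the times. Symbols are those of the tables. Without a strand setting, genes whose exons overlap another gene cannot be separated from it, so list members with a large overlap (Tagln, with 67.9% of its exon length shared, and Itgam, with 68.7%, for example) were counted in their lists and not named as examples. Members of gene families with near-identical sequences, such as the H2 class II genes, ribosomal protein genes and olfactory receptor genes, are reported as uncertain.

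Counts were analysed in R 4.3.3. The test of each comparison was the quasi-likelihood F-test of edgeR 4.0.16 with TMM scaling, the package's filter on low counts applied to the groups, and Benjamini-Hochberg adjustment, and a gene was called when its adjusted p was under 0.05. The comparisons of KO with control were fitted on the 8 libraries of each time. The change of the KO effect from 2 to 8 weeks (the interaction), the comparisons of the times within controls and within KO, and the difference of the KO effect between sexes were fitted on all 16 libraries. The sex model added sex and its product with genotype, and its values are male minus female. Standard errors of log2 fold changes were derived from the F statistic. Group levels are means ± SD of CPM, the counts scaled to library size with TMM factors over the libraries of the fit, with n = 4 in every group, and levels of single libraries are CPM scaled over all 16. Overlaps of calls between times were tested with a 2-sided Fisher exact test among genes tested in both fits. No animal was shared between times.

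Gene lists were tested with camera (limma 3.58.1, preset correlation of 0.01 between genes), adjusted over the 40 lists, and again with the correlation estimated from the data. The self-contained test fry was run beside it. The lists were YAP/TAZ-TEAD target genes, Hippo pathway and TEAD components, smooth muscle contractile genes, SRF/MRTF cytoskeletal genes, elastic fibre genes, fibrillar and network collagens, basement membrane genes, proteoglycan genes, matrix proteases and inhibitors, cartilage genes, bone and mineralization genes, TGF-beta signalling genes, heritable thoracic aortic aneurysm genes, proliferation genes, inflammatory cytokine and chemokine genes, interferon response genes, complement genes, antigen presentation genes, unfolded protein response genes, collagen processing and secretion genes, cholesterol synthesis and uptake genes, cholesterol efflux and lipid handling genes, oxidative phosphorylation genes, Notch signalling genes, Wnt signalling genes, immediate-early genes, ion channels and receptors of arterial smooth muscle, and apoptosis and p53 response genes. Another 12 lists held markers of macrophages and monocytes, T and NK cells, B cells and plasma cells, neutrophils, endothelium, adventitial fibroblasts, adipocytes, cardiac and skeletal muscle, Schwann cells and neurons, mesothelium, erythroid cells, and lymphatic endothelium. Beside the calls over all genes, member counts were also adjusted over the list alone.

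The tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule took Yap1, Wwtr1 and Itga8; for each KO comparison, the 8 higher and 8 lower protein-coding called genes with the largest fold change, a mean of at least 5 CPM and no overlap between the groups; up to 4 members with the smallest p of each list described; and, by smallest p, up to 6 genes per direction of the interaction and 5 per direction of each time comparison. List tests in the interaction and the time comparisons were added after the data were seen.

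The alternatives were DESeq2 1.42.0, the size factors of DESeq2 within edgeR, no scaling beyond library size, no filter, a filter of 1 CPM in at least 4 libraries, sex as a covariate, a minimum log2 fold change of 1, 1 shared fit of all 16 libraries, protein-coding genes alone, and leaving out each library in turn. Fits without pairs or sets of libraries that stood apart were added after the data were seen. Other splits of the same libraries into groups of equal size were counted, all 35 for comparisons of 2 groups and 60 drawn for the interaction and the sex term.

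The gene fits and camera were tested on simulated counts with known fold changes, drawn from the means and sizes of the real libraries. In each run 66 or 67 genes were changed at each of 1.5-fold, 2-fold and 4-fold, and a list of 20 genes 1.5-fold. Genes were drawn independently, and other steps were not simulated. The real comparisons of KO with control called far more genes (14.8% and 30.5% of those tested). The recovery and false calls below thus need not carry over to real counts. On the 16751 genes of the 2-week comparison, edgeR recovered 7.46% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 83.3% of those changed 4-fold, with 3.67% of its calls false. At 8 weeks, with 17374 genes, these shares were 13.4%, 53.7%, 83.3% and 4.67%. For the interaction, with 18135 genes, they were 2.99%, 37.3%, 81.8% and 3.57%. Between the times, recovery of 2-fold changes was 52.2% in controls and 67.2% in KO, with 2.94% and 7.2% of calls false, the latter above the 5% aimed at. For the sex term recovery was 26.9%, with no false calls. DESeq2, which was not run for the sex term, recovered more in the other comparisons, and between 20.8% and 23.5% of its calls were false there. Python 3.11.15 was used for annotation and figures.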

Results

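Gene expression was measured by RNA sequencing of thoracic aortas from adult mice in which YAP and TAZ, coactivators of TEAD transcription factors at the end of the Hippo pathway, could be deleted in smooth muscle. Mice with floxed Yap1 and Wwtr1 alleles received 1 mg of tamoxifen a day in 5 injections at an age of 6 to 8 weeks, and aortas were taken 2 or 8 weeks after the first injection. KO animals carried Itga8-CreERT2 and controls had the floxed alleles without Cre, with 4 animals in each of the 4 groups. KO and control animals thus also differed in CreERT2 and in the Itga8 driver allele, and the comparisons do not separate these from the deletion. The 16 libraries held 37337088 to 44436971 counts, and 22710 to 24503 genes had at least 1 count. A single count was worth 0.0225 to 0.0268 CPM. Mitochondrial transcripts took between 0.867% of counts, in control replicate 192 at 2 weeks, and 5.28%, in KO replicate 223 at 8 weeks. The first principal component held 42.0% of the variance and parted KO from control libraries, and the second held 12.8%. Control replicate 192 stood apart from the other libraries on the third, which held 7.11%. Transcripts of Y-linked genes were at 208.8 CPM or more in the 6 libraries labelled male and at 0.051 CPM or less in the 10 labelled female, and Xist separated the same libraries.

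The deleted genes and the driver of Cre were examined first, in every library. Yap1 (ENSMUSG00000053110, mm10 chromosome 9, 7931999 to 8004596, minus strand) was at 72.6 to 79.2 CPM in the 4 KO libraries at 2 weeks and at 167 to 183.5 CPM in the 4 controls. At 8 weeks it was at 87.2 to 96.6 CPM in KO and at 143.8 to 173 CPM in controls. Its log2 fold change was -1.20 ± 0.09 at 2 weeks (SE, n = 4 per group, edgeR adjusted p = 0.000135) and -0.80 ± 0.08 at 8 weeks (edgeR adjusted p = 0.000167). Transcripts of Wwtr1, which encodes TAZ (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910, minus strand), were not lower in KO. They were at 243 ± 3.85 CPM in KO and 197 ± 22.4 CPM in controls at 2 weeks (log2 fold change 0.30 ± 0.11, edgeR adjusted p = 0.095), and at 233 ± 15.8 against 191 ± 24.8 CPM at 8 weeks (0.29 ± 0.11, edgeR adjusted p = 0.0643). The 8-week value passed without scaling (edgeR adjusted p = 0.0335), with the stricter filter (0.0446), without control replicate 226 (0.0468) and in females alone (0.043), with log2 fold changes of 0.30 to 0.37. Which exons were deleted is not given in the sources used here, so counts over the whole gene do not measure how much of either allele was recombined. Other aortic cells also contribute reads.

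Itga8 (ENSMUSG00000026768, chromosome 2, 12106632 to 12301922, minus strand), the integrin gene that drives Cre in KO animals, was at 672 to 1105 CPM in the 8-week KO libraries and at 3240 to 4326 CPM in their controls, a log2 fold change of -2.03 ± 0.16 (edgeR adjusted p = 4.97e-05). In the shared fit of all 16 libraries this 8-week change did not pass (edgeR adjusted p = 0.0644). At 2 weeks, 3 KO libraries held 871 to 1495 CPM and replicate 222 held 4.85 CPM, against 3327 to 4777 CPM in controls. With this spread the 2-week change of -2.10 ± 1.00 did not pass (edgeR adjusted p = 0.193), and without replicate 222 it was -1.69 ± 0.22 (edgeR adjusted p = 0.00398).

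**Figure D1:**
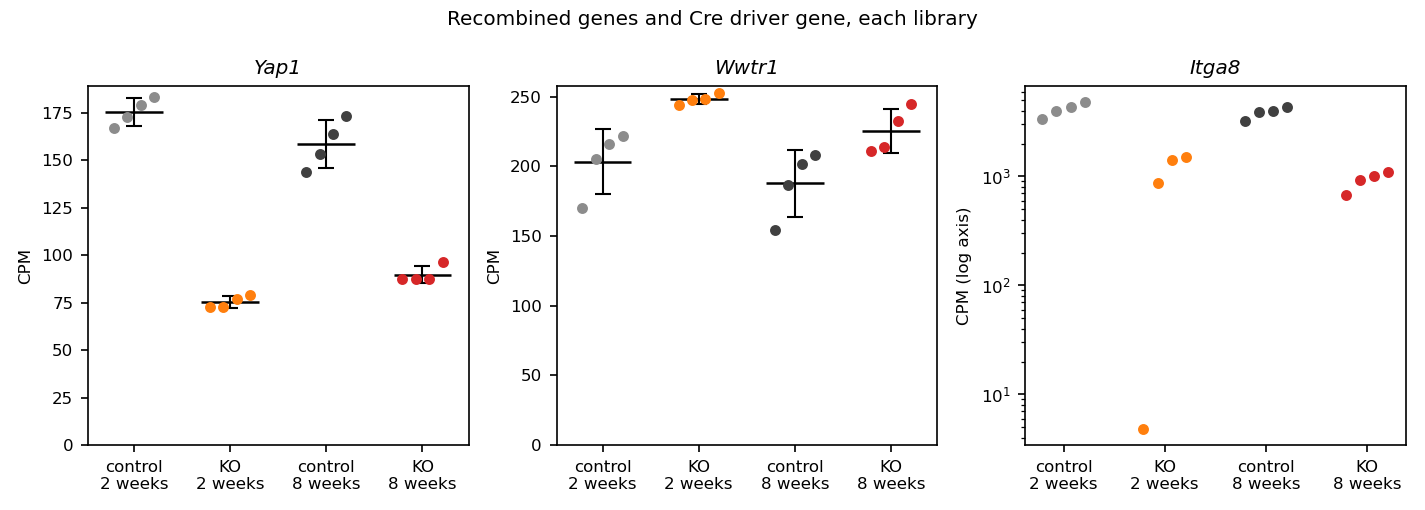
Levels of Yap1, Wwtr1 and Itga8 in CPM (y axis; the Itga8 axis is logarithmic) in the 4 groups, with 1 point per library; bars show mean and SD for Yap1 and Wwtr1. Yap1 stayed below 97 CPM in every KO library and above 143 CPM in every control, Wwtr1 did not fall, and Itga8 in KO replicate 222 at 2 weeks was at 4.85 CPM.

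KO and control aortas at 2 weeks were the subject of the first comparison. Of 24 contractile genes 13 were lower in KO aortas, while 19 of 20 proliferation genes, 13 of 19 cytokine and chemokine genes and 9 of 17 bone genes were higher. No list passed camera with an estimated correlation between genes. The test fry does not compare a list with the other genes, and so asks less. These lists passed it (fry adjusted p = 0.00968 for contractile, proliferation and bone genes, 0.0121 for cytokine and chemokine genes). Neutrophil (fry adjusted p = 0.0559) and adipocyte markers (0.0651), among the lists that passed camera with the preset correlation, did not. Acta2, the smooth muscle actin, fell from 17206 ± 5700.0 CPM in controls to 5026 ± 1254 CPM in KO (SD, n = 4 each, log2 fold change -1.78 ± 0.26, edgeR adjusted p = 0.00211). Spp1, which encodes the secreted matrix protein osteopontin, rose from 1.02 ± 0.185 to 673 ± 850 CPM (9.36 ± 1.48, edgeR adjusted p = 0.00332). Of 16751 genes tested, 2477 were called, 1430 higher and 1047 lower in KO, and of these 870 and 404 changed at least 2-fold. KO and control values did not overlap for 23.7% of genes tested, where chance gives 2.86%.

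Among the 8 protein-coding genes with the largest rise at 2 weeks were the cytokine genes Il6 (log2 fold change 8.23 ± 1.36, edgeR adjusted p = 0.0041) and Il1b (5.26 ± 0.87, 0.00404), the chemokine gene Cxcl14 (6.93 ± 1.19, 0.00492), Nos2, which encodes inducible nitric oxide synthase (6.15 ± 1.26, 0.011), and Lcn2, which encodes an iron-sequestering protein (5.95 ± 1.05, 0.00553). Slfn4 (5.65) and Dhrs9 (4.47) were the others beside Spp1, and Slfn4 is uncertain because it belongs to a family of similar genes. The 8 with the largest fall were Mybpc2, a myosin-binding protein gene (-4.58 ± 0.37, edgeR adjusted p = 0.000166), the receptor phosphatase gene Ptprz1 (-3.94 ± 0.24, 9.53e-05), the metalloprotease gene Adamts8 (-3.28), the cadherin gene Cdh3 (-3.07), the myosin kinase family gene Mylk4 (-2.75), Tent5b (-2.60), the leptin receptor gene Lepr (-2.57) and Sphkap (-2.57).

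Of 24 smooth muscle contractile genes, 13 fell and 11 did not pass (15 lower adjusted over the list alone). The contractile list had a median of -0.69 (camera adjusted p = 9.97e-09, adjusted p = 0.252 with an estimated correlation). Myl9, a myosin light chain (-1.67 ± 0.29), Myh11, the smooth muscle myosin heavy chain (-1.41 ± 0.26), Tpm1 (-1.15 ± 0.18) and Lmod1 (-0.96 ± 0.17) were among those that fell. Of 20 SRF/MRTF cytoskeletal genes, 7 fell, including Csrp1 (-1.67 ± 0.22), Fhl1 (-1.07 ± 0.15) and the focal adhesion gene Vcl (-0.77 ± 0.14), and 3 rose, including Tpm4 (0.88 ± 0.17). Adjusted over the list alone 8 and 3 did so. The median of this list was -0.02, and 0.05 without scaling (camera adjusted p = 0.0481, adjusted p = 0.583 with an estimated correlation). This camera call ended without KO replicate 195 (0.0734) or 218 (0.0792) or control replicate 192 (0.146) or 200 (0.0581). Flna fell by 1.22 with an edgeR adjusted p of 0.0151, which became 0.0505 without KO replicate 222. Of 21 ion channels and receptors of arterial smooth muscle, 5 fell, including Npr1 (-1.20 ± 0.17) and Itpr1 (-0.72 ± 0.16), and 2 rose (8 and 2 adjusted over the list alone, median -0.29). The camera test of that list passed narrowly (adjusted p = 0.0481, adjusted p = 0.427 with an estimated correlation), and did not without KO replicate 205 (0.053) or 218 (0.0824) or control replicate 192 (0.0524) or 200 (0.0619).

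Of 22 YAP/TAZ-TEAD target genes, 6 fell, 2 rose and 14 did not pass (7 and 3 adjusted over the list alone, median -0.16). Cyr61 (-2.35 ± 0.33) and Ctgf (-1.40 ± 0.26), both classical YAP targets, fell, as did Fjx1 (-1.14 ± 0.20) and Crim1 (-0.70 ± 0.12). The camera test of this list passed narrowly (adjusted p = 0.0481, adjusted p = 0.252 with an estimated correlation), and did not without KO replicate 195 (0.116) or 218 (0.0799) or control replicate 200 (0.0688). Of 18 Hippo pathway and TEAD components, 3 fell, among them Vgll4 (-0.61 ± 0.14) and Tead3 (-0.78 ± 0.18, edgeR adjusted p = 0.0182). Tead3 did not pass without KO replicate 218 (0.0577) or 222 (0.0548), and the list as a whole did not pass (median -0.05, and 0.02 without scaling, 3 lower adjusted over the list alone, camera adjusted p = 0.283).

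Of 20 proliferation genes, 19 rose (20 adjusted over the list alone), with a median of 2.54 (camera adjusted p = 1.03e-29, adjusted p = 0.252 with an estimated correlation). They included the cyclin genes Ccnb1 (3.33 ± 0.35) and Ccna2 (2.58 ± 0.29) and the mitotic kinesin gene Kif11 (2.48 ± 0.29). Of 19 inflammatory cytokine and chemokine genes, 13 rose, among them the monocyte attractant genes Ccl2 (3.17 ± 0.31) and Ccl7 (2.97 ± 0.45), and Cxcl12 (1.33 ± 0.15). Adjusted over the list alone 15 rose, and the median was 1.59 (camera adjusted p = 2.69e-13, adjusted p = 0.252 with an estimated correlation). Of 15 complement genes, 5 rose (7 higher and 1 lower adjusted over the list alone, median 0.61, camera adjusted p = 0.00749, adjusted p = 0.512 with an estimated correlation). Of 14 antigen presentation genes, 2 rose, and 2 did adjusted over the list alone (median 0.54, camera adjusted p = 0.0422, adjusted p = 0.637 with an estimated correlation). That call ended without KO replicate 218 (0.197) or control replicate 198 (0.174) or 202 (0.0956).

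Markers of other cells moved in the same libraries. Of 16 macrophage and monocyte markers, 10 rose, including Cx3cr1 (1.51 ± 0.31), Cd68 (1.22 ± 0.25) and Ccr2 (2.83 ± 0.63). The macrophage list alone gave 15 higher and 1 lower, with a median of 0.82 (camera adjusted p = 1.37e-06, adjusted p = 0.398 with an estimated correlation). All 5 measured neutrophil markers rose, including Il1r2 (3.97 ± 0.73), S100a9 (3.65 ± 0.80) and Csf3r (2.67 ± 0.60) (5 adjusted over the list alone). The neutrophil list had a median of 3.65 (camera adjusted p = 0.000763, adjusted p = 0.398 with an estimated correlation). The rise was not seen in every KO library. Averaged over 8 neutrophil markers, log2 CPM relative to the mean of all libraries was -0.50 in KO replicate 195. That lay within the controls at 2 weeks (-0.83 to -0.40), and the other KO libraries of that time were at 1.45 to 2.09. Of 9 T and NK cell markers 4 rose (4 adjusted over the list alone, median 1.23, camera adjusted p = 0.0108, adjusted p = 0.335 with an estimated correlation). Of 16 adipocyte markers 8 rose, including Fabp4 (1.45 ± 0.28) and Dio2 (1.202 ± 0.24) (10 adjusted over the list alone). The adipocyte list had a median of 1.44 (camera adjusted p = 2.13e-05, adjusted p = 0.432 with an estimated correlation). Of 7 lymphatic endothelial markers 2 rose, including Lyve1 (1.21 ± 0.15) (2 adjusted over the list alone). The lymphatic endothelial list had a median of 0.67 (camera adjusted p = 0.0108, adjusted p = 0.252 with an estimated correlation). Of 7 erythroid markers 1 rose (5 adjusted over the list alone, median 1.16, camera adjusted p = 0.0172, adjusted p = 0.551 with an estimated correlation), a camera call that ended without KO replicate 205 (0.0541) or control replicate 192 (0.0524).

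Endothelial markers did not pass as a list at 2 weeks (camera adjusted p = 0.29, 0.0366 without control replicate 192), and of its 15 members Emcn (2.07 ± 0.25) and Kdr (1.57 ± 0.25) were among 3 that rose and Cldn5 (-0.93 ± 0.20) fell (3 and 3 adjusted over the list alone). The median of 0.08 was -0.07 without control replicate 198 and -0.02 without 200. Kdr did not pass in the shared fit of all libraries (edgeR adjusted p = 0.0654), nor did Fabp4 (0.0987). Of 14 adventitial fibroblast markers 1 rose and 2 fell, namely Clec3b (-0.99 ± 0.21) and Scara5 (-0.59 ± 0.13), with 2 in each direction adjusted over the list alone. The median of -0.03 (0.04 without scaling, 0.01 without KO replicate 205) and the mean of 0.39 differed in sign (camera adjusted p = 0.657, downward). Schwann cell and neuron markers had 2 higher, and 2 lower including Prx (-1.04 ± 0.11), of 12 (3 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 0.416). Cardiac and skeletal muscle markers had 3 higher and 2 lower of 11 (3 and 4 adjusted over the list alone, median 0.43, camera adjusted p = 0.975). Mesothelial markers had 1 higher of 9 (1 adjusted over the list alone, median 0.30, but -0.01 without control replicate 202, camera adjusted p = 0.329). None of 4 B cell and plasma cell markers passed in edgeR over all genes or adjusted over the list alone, though 3 had an unadjusted p under 0.05 (median 1.22, camera adjusted p = 0.316).

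Matrix transcripts rose in several classes at 2 weeks. Of 15 measured cartilage genes, 7 rose, including Sox9, a chondrocyte transcription factor gene (2.37 ± 0.22), and Cilp (1.59 ± 0.16), and 2 fell, including Cytl1 (-0.999 ± 0.16). Adjustment over the list alone gave 8 and 2, with a median of 1.23 (camera adjusted p = 0.000471, adjusted p = 0.252 with an estimated correlation). Of 17 bone and mineralization genes, 9 rose, including Ank (1.22 ± 0.16), Postn (1.08 ± 0.15) and Bmp4 (0.81 ± 0.13) (13 adjusted over the list alone). The bone list had a median of 1.08 (camera adjusted p = 3.98e-07, adjusted p = 0.252 with an estimated correlation). Of 15 fibrillar and network collagens, 6 rose, including Col12a1 (2.38 ± 0.30), Col8a1 (2.64 ± 0.53) and Col15a1 (1.13 ± 0.13) (7 adjusted over the list alone). The collagen list had a median of 0.52 (camera adjusted p = 3.08e-06, adjusted p = 0.252 with an estimated correlation). Of 20 proteoglycan genes, 6 rose, including Acan (3.30 ± 0.26), Vcan (1.48 ± 0.19) and Prg4 (3.49 ± 0.77), and Ogn fell (-1.19 ± 0.23). Adjusted over the list alone 7 were higher and 3 lower. Its median was 0.35 (camera adjusted p = 0.0172, and 0.106 without control replicate 192, adjusted p = 0.355 with an estimated correlation).

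Of 17 basement membrane genes, 4 rose, including Col4a6 (1.12 ± 0.13) (6 adjusted over the list alone). The basement membrane list had a median of 0.30 (camera adjusted p = 0.0172, adjusted p = 0.432 with an estimated correlation), a call that ended without KO replicate 195 (0.115) or control replicate 198 (0.0706). Of 20 collagen processing and secretion genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.00749, adjusted p = 0.517 with an estimated correlation). Of 20 unfolded protein response genes 5 rose (9 adjusted over the list alone, median 0.27, camera adjusted p = 0.0172, and 0.0655 without KO replicate 195, adjusted p = 0.329 with an estimated correlation). Of 20 matrix proteases and inhibitors, 4 rose, including Timp1 (3.79 ± 0.61), and 5 fell, including Mmp17 (-1.66 ± 0.22), with 5 and 7 adjusted over the list alone. The median of -0.06 and the mean of 0.17 differed in sign (camera adjusted p = 0.298, downward), and the median was 0.001 without scaling, 0.03 without KO replicate 205 and 0.08 without control replicate 202. Of 18 elastic fibre genes 3 rose and 1, Ltbp1 (-0.74 ± 0.14), fell, the same numbers as adjusted over the list alone (median 0.20, camera adjusted p = 0.479). Lox, which encodes a collagen and elastin cross-linking enzyme, was among those that rose (0.88 ± 0.22, edgeR adjusted p = 0.0263), and did not pass without KO replicate 218 (0.0701) or 222 (0.0715) or control replicate 198 (0.0606) or 200 (0.0523).

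The remaining lists did not pass the camera test at 2 weeks. Of 18 TGF-beta signalling genes 3 rose, including Thbs1 (2.27 ± 0.25), and 2 fell (4 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.346). Of 19 heritable thoracic aortic aneurysm genes, which include Acta2 and Myh11, 4 rose and 5 fell (4 and 5 adjusted over the list alone, median -0.06, and 0.006 without scaling, camera adjusted p = 0.386). Of 13 Notch signalling genes 2 fell, the receptor genes Notch3 (-1.56 ± 0.28) and Notch2 (-0.67 ± 0.15), with 2 adjusted over the list alone (median -0.13, camera adjusted p = 0.239). Of 15 Wnt signalling genes 2 rose, including Sfrp1 (1.07 ± 0.15), and Nkd1 fell (-1.07 ± 0.11), with 3 and 1 adjusted over the list alone (median 0.37, camera adjusted p = 0.283). Of 18 immediate-early genes 2 rose and 2 fell, including Nr4a1 (-1.78 ± 0.38), with 4 and 4 adjusted over the list alone (median -0.58, camera adjusted p = 0.208, but 0.0424 without control replicate 198 and 0.0348 without 192). Of 18 apoptosis and p53 response genes 2 rose, including Cdkn1a (0.67 ± 0.12), and 2 fell, including Cdkn2b (-1.45 ± 0.22), the same numbers as adjusted over the list alone (median 0.18, camera adjusted p = 0.657). Of 16 cholesterol efflux and lipid handling genes 5 rose and 2 fell (8 and 3 adjusted over the list alone, median 0.53, camera adjusted p = 0.0788, but 0.0246 without KO replicate 205). Of 17 cholesterol synthesis and uptake genes 1 rose (1 adjusted over the list alone, median 0.04, camera downward, adjusted p = 0.672). None of 18 interferon response genes passed in edgeR over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05 (median 0.48, camera adjusted p = 0.0788, but 0.0333 without KO replicate 195 and 0.00377 without control replicate 200). None of 20 oxidative phosphorylation genes passed in either way, nor at an unadjusted p under 0.05 (median 0.01, mean -0.008, camera adjusted p = 0.971).

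The number of calls at 2 weeks fell without most single libraries. It was 1546, 1628 and 1977 without KO replicates 218, 222 and 205. Without control replicates 200, 202 and 198 it was 1718, 1766 and 1791. It rose to 2619 without KO replicate 195 and to 2922 without control replicate 192, and was 2313 without both KO replicate 222 and control replicate 192. The authors' deposited table held 3509 genes past an adjusted p of 0.05, 2015 higher and 1494 lower, and 2470 of the 2477 edgeR calls were among them.

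**Figure D2:**
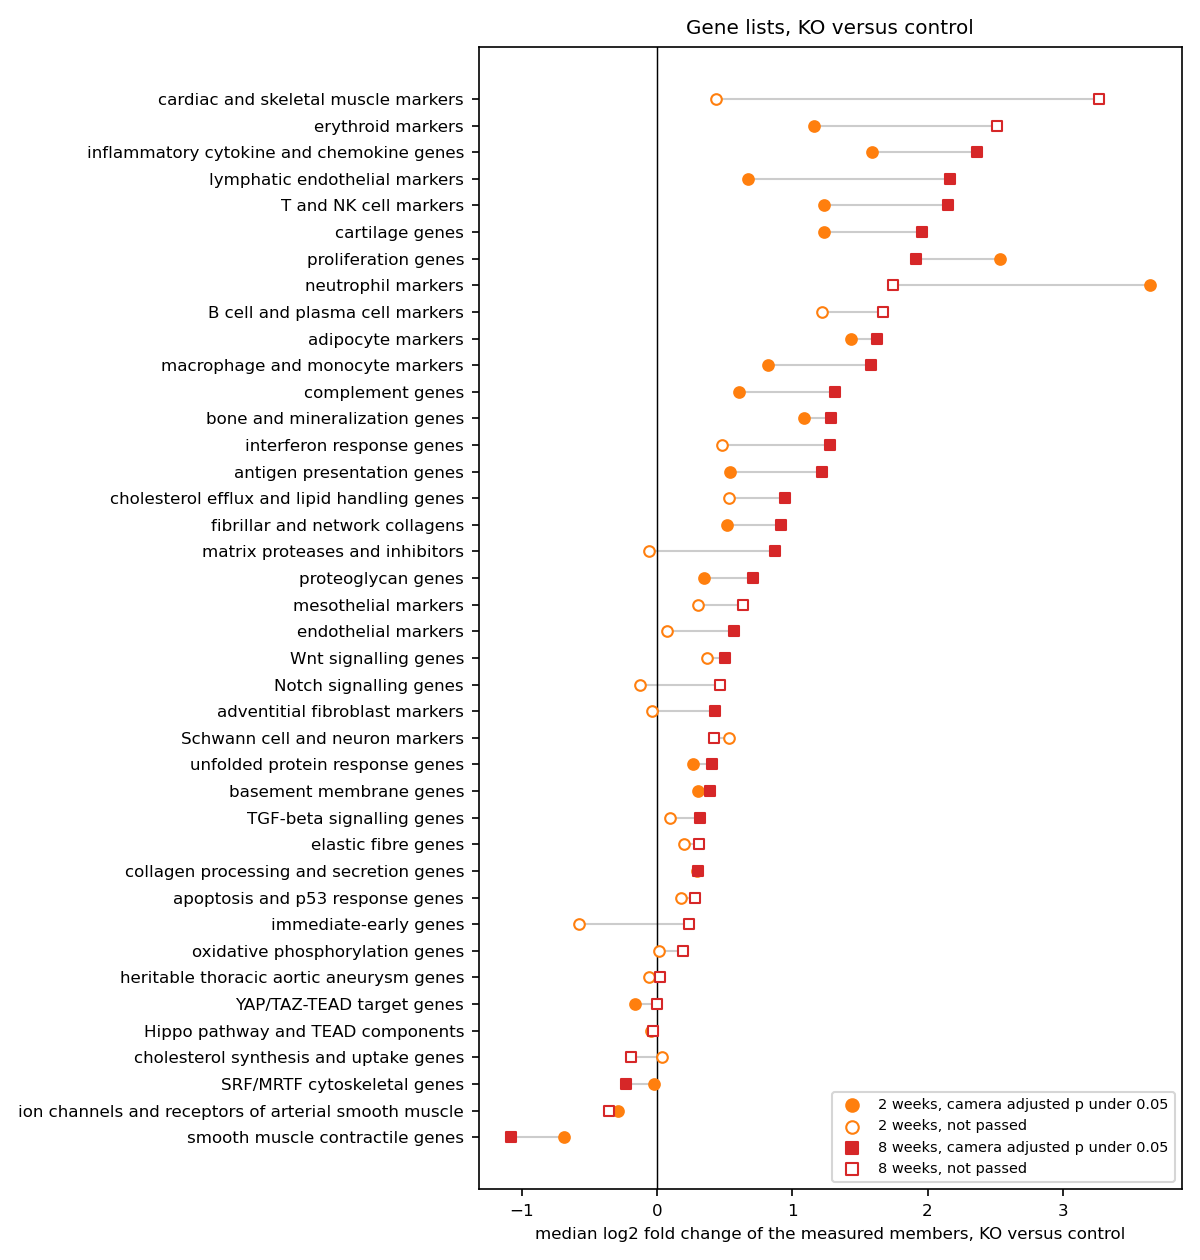
Median log2 fold change of KO over control (x axis) of the measured members of each of the 40 gene lists (y axis) at 2 weeks (circles) and 8 weeks (squares), with filled symbols where the camera test passed. Proliferation genes had medians of 2.54 and 1.92, contractile genes of -0.69 and -1.08, and the 8-week median of cardiac and skeletal muscle markers rested on 1 KO library.

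At 8 weeks, KO aortas were again compared with controls. Most contractile genes were lower than in controls, and most genes of the cartilage, cytokine, antigen presentation and proliferation lists were higher. None of these lists passed camera with an estimated correlation between genes. Acta2 fell from 14530 ± 1484 CPM in controls to 3415 ± 790.3 CPM in KO (log2 fold change -2.09 ± 0.19, edgeR adjusted p = 8.18e-05), and Spp1 rose from 0.52 ± 0.167 to 756 ± 327 CPM (10.50 ± 0.46, edgeR adjusted p = 2.06e-06). Of 17374 genes tested, 5296 were called, 3100 higher and 2196 lower, and of these 1670 and 591 changed at least 2-fold. KO and control values did not overlap for 32.5% of genes, where chance gives 2.86%.

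The 8 protein-coding genes with the largest rise at 8 weeks included Col2a1, the main fibrillar collagen of cartilage (9.31 ± 2.01, edgeR adjusted p = 0.00708), Col11a1 (5.98 ± 0.76, 0.000494) and Col10a1, a collagen of hypertrophic chondrocytes (6.34 ± 0.71, 0.000266). Cemip, which encodes a hyaluronan-degrading protein (8.38 ± 0.52), Scg2 (8.24 ± 0.74), Lcn2 (6.49 ± 0.53) and Olfr558 (6.06 ± 0.63) were the others beside Spp1, and Olfr558 is uncertain as a member of a family of similar genes. The 8 with the largest fall were Mybpc2 (-4.66 ± 0.34, edgeR adjusted p = 3.32e-05), Ptprz1 (-4.23 ± 0.33), Fam19a1 (-3.77), Mylk4 (-3.74 ± 0.10), Klk10 (-3.72), the potassium channel gene Kcnc4 (-3.59), Vstm2b (-3.40) and Eppk1 (-3.08).

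Of 24 smooth muscle contractile genes 21 fell, 1 rose and 2 did not pass (22 and 1 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 1.13e-17, adjusted p = 0.12 with an estimated correlation). Ppp1r14a, a myosin phosphatase inhibitor gene (-2.26 ± 0.21), Myh11 (-2.07 ± 0.23), Myl9 (-1.93 ± 0.16) and Tpm1 (-1.49 ± 0.10) were among those that fell. Of 20 SRF/MRTF cytoskeletal genes 10 fell, including Csrp1 (-1.92 ± 0.13), Flna (-1.55 ± 0.19) and Srf itself (-0.93 ± 0.08), and 3 rose, including Fhl2 (3.30 ± 0.22) and Tpm4 (0.85 ± 0.09). Adjusted over the list alone 10 and 4 did so. Its median was -0.23 (camera adjusted p = 0.00287, and 0.0626 without KO replicate 228, adjusted p = 0.371 with an estimated correlation). Of 21 ion channels and receptors of arterial smooth muscle, 5 rose, including Kcna5 (2.44 ± 0.31) and the endothelin receptor gene Ednra (1.46 ± 0.19), and 7 fell, including Npr1 (-1.45 ± 0.11), with 5 and 8 adjusted over the list alone. The median of -0.35 and the mean of 0.14 differed in sign (camera adjusted p = 0.181, downward).

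YAP/TAZ-TEAD target genes moved both ways at 8 weeks. Of 22, 7 rose, including Nuak2 (2.19 ± 0.28), Nt5e (1.05 ± 0.17) and Ccdc80 (0.98 ± 0.12), and 4 fell, including Fjx1 (-1.60 ± 0.10), with 8 and 5 adjusted over the list alone. The median of -0.003 (0.02 without scaling) and the mean of 0.19 differed in sign (camera adjusted p = 0.982, downward). That median was 0.15 without KO replicate 228, 0.12 without 229 or 230 and 0.11 without control replicate 234. Of 18 Hippo pathway and TEAD components 1 rose and 1 fell, Tead3 (-1.02 ± 0.13), the same numbers as adjusted over the list alone (median -0.03, camera adjusted p = 0.474).

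Of 20 proliferation genes 18 rose, including Top2a (2.56 ± 0.26), Cdk1 (2.85 ± 0.30) and Ccna2 (1.98 ± 0.22) (18 adjusted over the list alone). The proliferation list had a median of 1.92 (camera adjusted p = 1.46e-11, adjusted p = 0.337 with an estimated correlation). Of 19 inflammatory cytokine and chemokine genes 18 rose, including Cx3cl1 (2.07 ± 0.22), Il1b (4.68 ± 0.52) and the adhesion molecule genes Sele (3.56 ± 0.26) and Icam1 (1.47 ± 0.15) (19 adjusted over the list alone). The cytokine list had a median of 2.36 (camera adjusted p = 2.06e-14, adjusted p = 0.12 with an estimated correlation). Of 18 interferon response genes 14 rose, including Oas1a (2.08 ± 0.24), Irf7 (1.95 ± 0.30) and Ifit3 (1.44 ± 0.26) (16 adjusted over the list alone). The interferon response list had a median of 1.28 (camera adjusted p = 3.35e-06, adjusted p = 0.371 with an estimated correlation). Of 14 complement genes 13 rose, including the receptor genes C5ar1 (1.88 ± 0.17) and C3ar1 (1.86 ± 0.25) (13 adjusted over the list alone). The complement list had a median of 1.32 (camera adjusted p = 1.74e-08, adjusted p = 0.337 with an estimated correlation). All 14 antigen presentation genes rose, including H2-Eb1 (2.29 ± 0.33) and H2-Aa (2.14 ± 0.31), which are uncertain as members of a family of similar genes (14 adjusted over the list alone). The antigen presentation list had a median of 1.22 (camera adjusted p = 1.22e-08, adjusted p = 0.366 with an estimated correlation).

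Beside these, 15 of 16 macrophage and monocyte markers rose, including Trem2 (3.35 ± 0.24), Cx3cr1 (2.48 ± 0.30), Fcgr1 (2.27 ± 0.23) and C1qa (1.55 ± 0.19) (15 adjusted over the list alone). The macrophage list had a median of 1.58 (camera adjusted p = 3.85e-13, adjusted p = 0.319 with an estimated correlation). Of 11 T and NK cell markers 8 rose (8 adjusted over the list alone, median 2.15, camera adjusted p = 0.00101, adjusted p = 0.371 with an estimated correlation). Of 15 endothelial markers 6 rose, including Emcn (2.85 ± 0.15), Erg (0.98 ± 0.11) and Cdh5 (0.95 ± 0.23) (6 adjusted over the list alone). The endothelial list had a median of 0.57 (camera adjusted p = 0.00282, adjusted p = 0.371 with an estimated correlation). Of 7 lymphatic endothelial markers 6 rose, including Reln (2.17 ± 0.22) and Flt4 (1.69 ± 0.21) (7 adjusted over the list alone). The lymphatic endothelial list had a median of 2.17 (camera adjusted p = 2.81e-06, adjusted p = 0.192 with an estimated correlation). Of 14 adventitial fibroblast markers 7 rose, including Cxcl14 (5.94 ± 0.78), Lum (2.02 ± 0.22) and Dpt (1.07 ± 0.10), and 2 fell, including Clec3b (-0.98 ± 0.16), the same numbers as adjusted over the list alone (median 0.43, camera adjusted p = 0.0139, adjusted p = 0.479 with an estimated correlation). Of 16 adipocyte markers 3 rose, including Retn (3.21 ± 0.65) and Cfd (3.49 ± 0.83), the same number as adjusted over the list alone (median 1.63, camera adjusted p = 0.00525, adjusted p = 0.515 with an estimated correlation). The groups overlapped on this list. Averaged over the markers, log2 CPM relative to the mean of all libraries ran from 0.05 to 2.35 in KO and from -2.50 to 1.26 in controls.

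Other cell markers did not pass as lists at 8 weeks. Of 9 B cell and plasma cell markers 3 rose (3 adjusted over the list alone, median 1.67, camera adjusted p = 0.0704), a test that passed without KO replicate 229 (0.0488) or 230 (0.0117) or control replicate 236 (0.00419). Of 4 neutrophil markers 2 rose, including Csf3r (1.74 ± 0.45), with 2 adjusted over the list alone (median 1.74, camera adjusted p = 0.143). Of 7 erythroid markers 4 rose (5 adjusted over the list alone, median 2.51, camera adjusted p = 0.105, but 0.0434 without KO replicate 228 and 0.0107 without 230). Of 12 Schwann cell and neuron markers 3 rose, including S100b (1.75 ± 0.12), and 2 fell, including Prx (-0.85 ± 0.09), the same numbers as adjusted over the list alone (median 0.42, camera adjusted p = 0.286). Of 7 mesothelial markers 1 rose (1 adjusted over the list alone, median 0.64, camera adjusted p = 0.217, but 0.000618 without control replicate 231). Of 14 cardiac and skeletal muscle markers 4 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 0.216), and the median of 3.27 became -0.42 without KO replicate 223.

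Of 15 cartilage genes 9 rose, including Sox9 (4.27 ± 0.30) and Comp (3.71 ± 0.38), and 3 fell (11 and 3 adjusted over the list alone). The cartilage list had a median of 1.96 (camera adjusted p = 0.000228, adjusted p = 0.337 with an estimated correlation). Of 17 bone and mineralization genes 13 rose, including Phex (3.22 ± 0.14), the decoy receptor gene Tnfrsf11b (2.96 ± 0.12) and Ank (1.29 ± 0.10) (14 adjusted over the list alone). The bone list had a median of 1.29. It was the only list at either time to hold with an estimated correlation (camera adjusted p = 3.39e-18, adjusted p = 0.021 with an estimated correlation). Of 20 proteoglycan genes 12 rose, including Acan (4.18 ± 0.23), Lum (2.02 ± 0.22) and Fmod (1.58 ± 0.16), and 2 fell (13 and 2 adjusted over the list alone). The proteoglycan list had a median of 0.71 (camera adjusted p = 3.31e-06, adjusted p = 0.337 with an estimated correlation). Of 15 fibrillar and network collagens 12 rose, including Col8a1 (4.70 ± 0.60), Col12a1 (2.87 ± 0.25) and Col1a1 (1.26 ± 0.13) (13 adjusted over the list alone). The collagen list had a median of 0.92 (camera adjusted p = 5.27e-09, adjusted p = 0.192 with an estimated correlation). Of 20 matrix proteases and inhibitors 11 rose, including the macrophage elastase gene Mmp12 (4.96 ± 0.40) and Timp1 (2.58 ± 0.34), and 3 fell, including Adamts8 (-3.02 ± 0.22) and Mmp17 (-2.04 ± 0.18) (13 and 3 adjusted over the list alone). The matrix protease list had a median of 0.87 (camera adjusted p = 0.0133, adjusted p = 0.371 with an estimated correlation).

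Of 17 basement membrane genes 10 rose, including Lama3 (2.22 ± 0.12) and Nid2 (1.14 ± 0.15), and 2 fell, including Lama4 (-0.57 ± 0.10) (11 and 3 adjusted over the list alone). The basement membrane list had a median of 0.39 (camera adjusted p = 0.00612, adjusted p = 0.371 with an estimated correlation). Of 18 elastic fibre genes 9 rose, including Lox (1.01 ± 0.13) and Ltbp2 (1.96 ± 0.27), and 2 fell (9 and 3 adjusted over the list alone). The elastic fibre list had a median of 0.31. The camera test of that list gave an adjusted p of 0.0573, and passed without KO replicate 223 (0.0354), 229 (0.0488) or 230 (0.0258) or control replicate 226 (0.0444) or 234 (0.0391). Of 20 collagen processing and secretion genes 12 rose (12 adjusted over the list alone, median 0.30, camera adjusted p = 0.00394, adjusted p = 0.371 with an estimated correlation), and of 20 unfolded protein response genes 12 rose (17 higher and 1 lower adjusted over the list alone, median 0.41, camera adjusted p = 0.00242, adjusted p = 0.371 with an estimated correlation). Of 18 TGF-beta signalling genes 7 rose, including Thbs1 (2.95 ± 0.14), and 3 fell, including Tgfbi (-0.91 ± 0.11) (10 and 3 adjusted over the list alone). The TGF-beta list had a median of 0.32 (camera adjusted p = 0.0111, adjusted p = 0.192 with an estimated correlation). Of 19 heritable thoracic aortic aneurysm genes 5 rose and 7 fell, with 7 in each direction adjusted over the list alone. The median of 0.02 and the mean of -0.24 differed in sign (camera adjusted p = 0.16, downward, and 0.023 without KO replicate 223).

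Of 16 cholesterol efflux and lipid handling genes 11 rose, including Apoe (1.27 ± 0.14), the scavenger receptor gene Msr1 (2.13 ± 0.23) and Fabp5 (2.03 ± 0.23), and 2 fell (12 and 2 adjusted over the list alone). The lipid handling list had a median of 0.95 (camera adjusted p = 0.000807, adjusted p = 0.371 with an estimated correlation). Of 17 cholesterol synthesis and uptake genes 3 fell, Vldlr (-1.01 ± 0.12), Srebf2 (-0.71 ± 0.13) and Lss (-0.68 ± 0.13), and 1 rose, the same numbers as adjusted over the list alone (median -0.19, camera adjusted p = 0.139, but 0.0442 without KO replicate 230 and 0.02 without control replicate 236). Of 15 Wnt signalling genes 7 rose, including Nkd2 (1.60 ± 0.17), Sfrp1 (1.26 ± 0.13) and Dkk3 (0.80 ± 0.10), and 2 fell, as adjusted over the list alone (median 0.50, camera adjusted p = 0.0128, adjusted p = 0.371 with an estimated correlation). Of 13 Notch signalling genes 6 rose, including Notch3 (1.85 ± 0.26), and Notch2 fell (-0.64 ± 0.08), with 7 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.181). Of 18 apoptosis and p53 response genes 7 rose, including Cdkn1a (1.11 ± 0.10), and 3 fell, including Fas (-0.997 ± 0.15), with 8 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.139). Of 18 immediate-early genes 4 rose, including Egr2 (2.03 ± 0.33) and Klf4 (0.69 ± 0.13), as adjusted over the list alone (median 0.24, camera adjusted p = 0.335, but 0.0407 without KO replicate 230). None of 20 oxidative phosphorylation genes passed in edgeR, over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (median 0.19, camera adjusted p = 0.43, but 0.0212 without control replicate 231). The authors' deposited table held 6084 genes past an adjusted p of 0.05 at 8 weeks, 3541 higher and 2543 lower, and 5230 of the 5296 edgeR calls were among them.

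**Figure D3:**
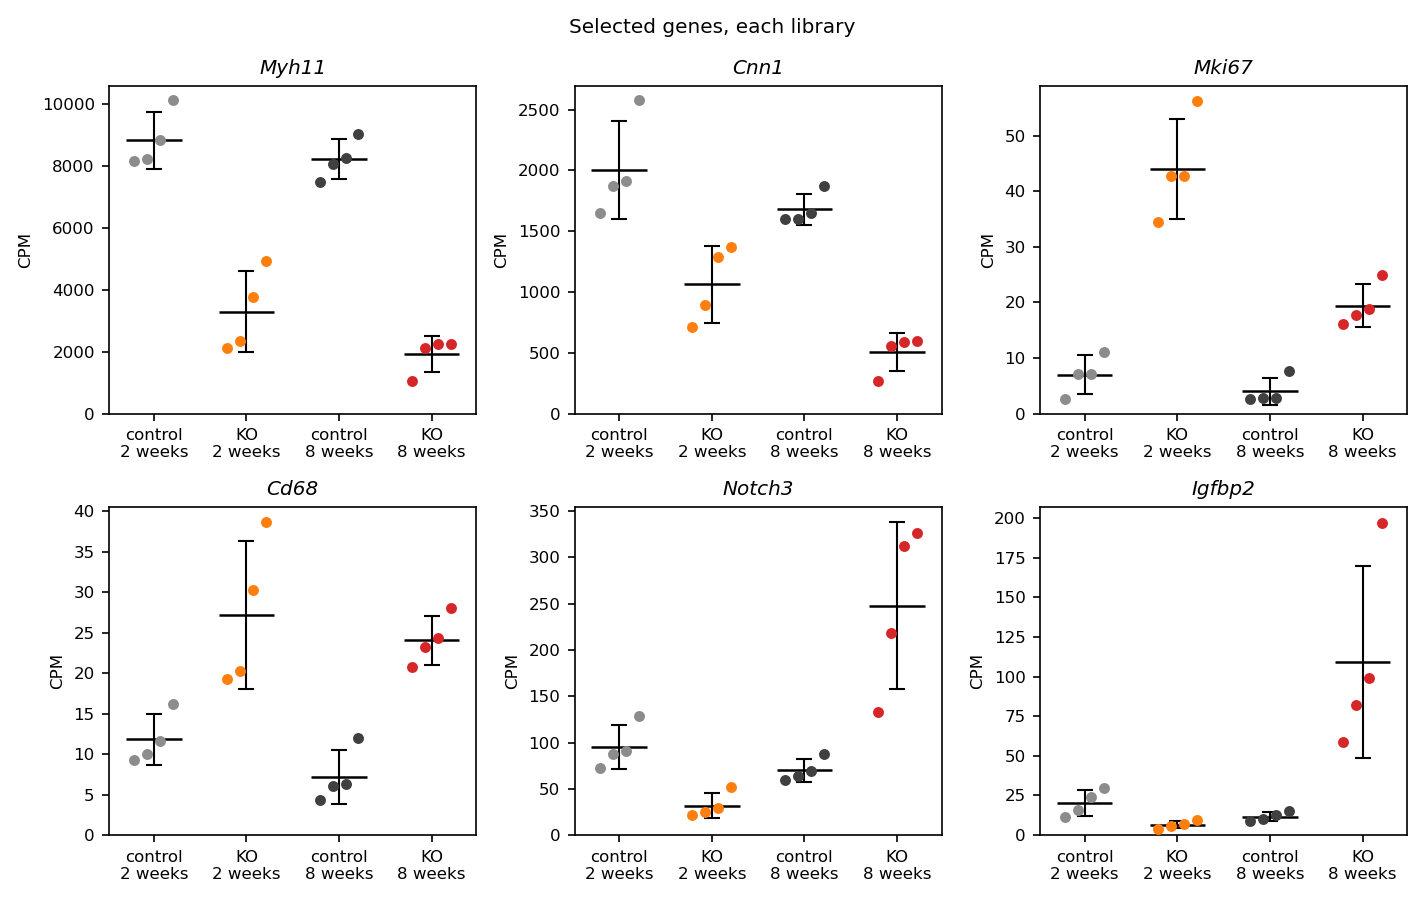
Levels in CPM (y axis) of Myh11, Cnn1, Mki67, Cd68, Notch3 and Igfbp2 in the 4 groups, with 1 point per library and the mean and SD of each group. Myh11 and Cnn1 were lower and Mki67 and Cd68 higher in KO at both times, and Notch3 and Igfbp2 lay below controls at 2 weeks and above them at 8 weeks.

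The effects at the times were then compared, since the series sampled both. Most genes called at 2 weeks moved the same way at 8 weeks: of 2459 called at 2 weeks and tested at both, 96.5% had the same sign. Among 16551 genes tested in both fits, 1121 were higher in KO at both times, against 254.9 for independent lists (Fisher exact odds ratio 27.3, 95% interval 23.7 to 31.4), and 739 were lower at both, against 136.7 (odds ratio 23.9, 20.6 to 27.6). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.776 and a Spearman rho of 0.682. Opposite calls were made for 10 genes. Of these, 9 were lower at 2 weeks and higher at 8 weeks, among them Notch3, a receptor of arterial smooth muscle (-1.56, then 1.85), Igfbp2, an insulin-like growth factor binding protein gene (-1.63, then 3.26), and Angpt2, an angiopoietin gene (-0.96, then 0.77). Creb5 was higher at 2 weeks (0.60) and lower at 8 weeks (-0.77).

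**Figure D4:**
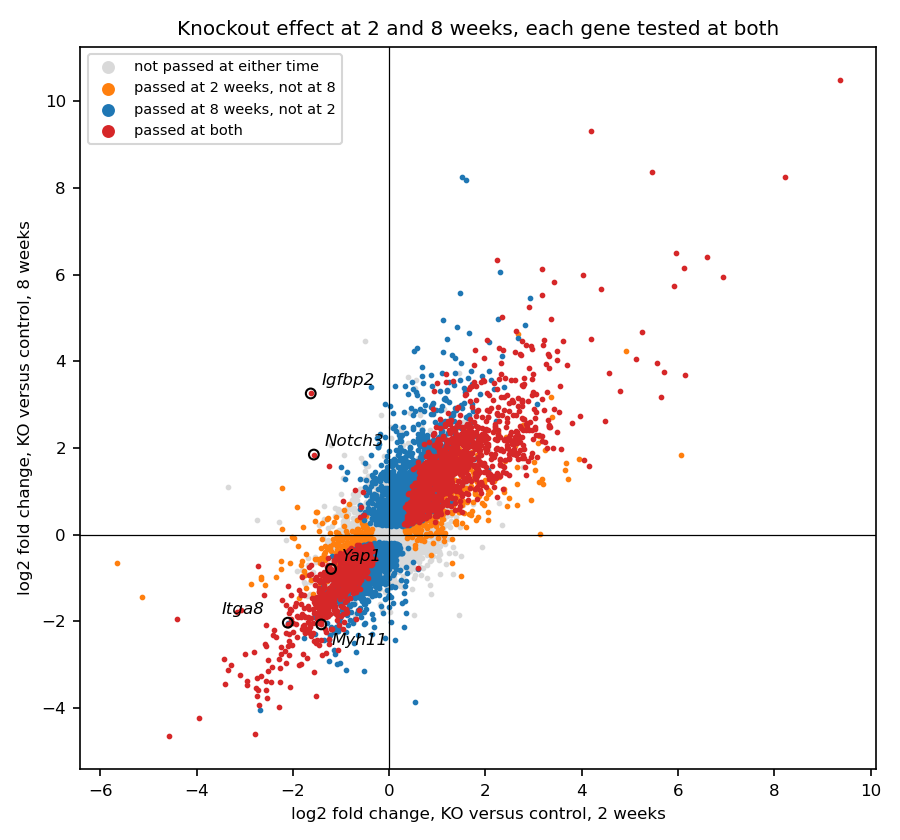
Log2 fold change of KO over control at 2 weeks (x axis) and 8 weeks (y axis), 1 point per gene tested at both times, coloured by the time at which the gene was called. The 1121 genes higher and 739 lower at both times lie along the diagonal, and Notch3 and Igfbp2 lie in the upper left.

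The test of the difference itself, the change of the KO effect from 2 to 8 weeks, called 116 of 18135 genes, 98 with a higher and 18 with a lower effect at 8 weeks. All 10 genes with opposite calls were among them, including Notch3 (change of 3.399 ± 0.41, edgeR adjusted p = 0.000745) and Igfbp2 (4.87 ± 0.53, 0.000244). By smallest p, the KO effect rose for the laminin gene Lama3 (2.46 ± 0.22, 6.2e-05), Cpxm2 (1.97 ± 0.18), Myo10 (1.72 ± 0.18), Cpz (1.55 ± 0.16), Igfbp2 and the protease gene Pappa2 (2.71 ± 0.30). Among the genes for which it fell were Lancl3 (-1.42 ± 0.22, edgeR adjusted p = 0.00567), Uhrf1bp1l (-0.77 ± 0.13), the nuclear import gene Kpna2 (-1.09 ± 0.20), Creb5 (-1.37 ± 0.27) and Usp13 (-0.79 ± 0.15). Yap1 itself did not pass (0.40 ± 0.11, edgeR adjusted p = 0.131, and 0.0185 with DESeq2), nor did Itga8 (0.06 ± 1.08, 0.989). The camera test passed for 18 of the 40 lists upward and 3 downward, and for none with an estimated correlation. Most called members were in the matrix protease list, then in the complement and cartilage lists: complement genes had 3 members called higher (6 adjusted over the list alone, median 0.67, camera adjusted p = 6.03e-09, adjusted p = 0.261 with an estimated correlation), cartilage genes 3 of 16 (5 higher and 1 lower adjusted over the list alone, median 1.23, camera adjusted p = 9.87e-06, adjusted p = 0.185 with an estimated correlation), and matrix proteases and inhibitors 4 (7 adjusted over the list alone, median 0.56, camera adjusted p = 6.09e-07, adjusted p = 0.127 with an estimated correlation). From 2 to 8 weeks the median of matrix proteases was -0.52 in controls and 0.02 in KO, that of complement genes -0.57 and 0.06, and that of cartilage genes -0.24 and 1.12. Chance was not excluded for the difference between control times, so these medians do not settle in which genotype the lists changed.

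The interaction count was 60 without KO replicate 223, 63 without control replicate 234, 67 without control replicate 236, 71 without KO replicate 205, 72 without control replicate 202 and 76 without KO replicate 195. Usp13 lost its call without KO replicate 205 (edgeR adjusted p = 0.0685) or 228 (0.054) or control replicate 198 (0.0514), 234 (0.0539) or 236 (0.0631). Creb5 lost it without KO replicate 223 (0.0506) or 228 (0.0511) or control replicate 202 (0.0527), 234 (0.0633) or 236 (0.064), and Kpna2 without control replicate 234 (0.0506).

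Control aortas at 8 weeks were compared with those at 2 weeks as the background of age and sampling day. Of 18135 genes 13 were called, all lower at 8 weeks, and 2519 had an unadjusted p under 0.05; the groups did not overlap for 5.75% of genes, where chance gives 2.86%. The carboxypeptidase gene Cpz (-1.01 ± 0.12, edgeR adjusted p = 0.00261), Galnt17 (-0.83 ± 0.10), the matrix gene Adamtsl2 (-1.62 ± 0.21), the chemerin receptor gene Cmklr1 (-0.89 ± 0.12) and Gdf15 (-2.85 ± 0.44, 0.0225) had the smallest p. None of the higher genes passed in edgeR, where Malt1 (0.66 ± 0.14) and the uncertain ribosomal gene Rpl21 (0.80 ± 0.17), which has many processed copies, had an adjusted p of 0.0818. Trim39 (0.55 ± 0.13, edgeR adjusted p = 0.109) and Tmem200a (2.01 ± 0.47, 0.111) were next, and Gm7233 had no counts in any control at 2 weeks. DESeq2 called 302 genes in this comparison, 92 higher and 210 lower. The edgeR count was 351 without control replicate 226 at 8 weeks, 157 higher and 194 lower, with Malt1 among them (adjusted p = 0.018), and 4 without control replicate 236, 6 without 234, 7 without 192, and 8 without control replicate 198 or 202 or without KO replicate 195. Gdf15 did not pass without control replicate 231 (edgeR adjusted p = 0.0605), 234 (0.0928) or 236 (0.147). The camera test passed for 25 of the 40 lists, all downward, and for none with an estimated correlation; all 9 mesothelial markers were lower adjusted over the list alone (median -2.07, camera adjusted p = 1.69e-09, adjusted p = 0.142 with an estimated correlation).

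Between KO aortas at 8 and 2 weeks, 1091 genes were called, 558 higher and 533 lower at 8 weeks, or 678 and 381 without scaling. The groups did not overlap for 18.9% of genes, where chance gives 2.86%. Cpxm2 (2.01 ± 0.13, edgeR adjusted p = 7.71e-07), Lama3 (1.95 ± 0.16), Myo10 (1.56 ± 0.13), C1qtnf7 (1.41 ± 0.12) and Pappa2 (2.33 ± 0.21) rose with the smallest p, and Lancl3 (-1.73 ± 0.16, 2.36e-05), the sodium-calcium exchanger gene Slc8a1 (-0.86 ± 0.10), Klk10 (-2.69 ± 0.33), Mylk4 (-1.25 ± 0.16) and Itih2 (-1.04 ± 0.14) fell. The camera test passed for 10 of the 40 lists upward and 11 downward, and for none with an estimated correlation. Of 20 proliferation genes 13 fell from 2 to 8 weeks in KO (20 adjusted over the list alone, median -1.25, camera adjusted p = 2.09e-17, adjusted p = 0.411 with an estimated correlation), while 18 of them were still higher than in controls at 8 weeks. The list fell in controls too (5 lower adjusted over the list alone, median -0.586, camera adjusted p = 1.41e-07, adjusted p = 0.234 with an estimated correlation). No member was called in the interaction in edgeR, but the median of the list there was -0.50, so the falls in KO and controls were not shown to be alike. Yap1 was 0.25 ± 0.08 higher at 8 weeks, which did not pass (edgeR adjusted p = 0.0666). It passed without scaling (0.0325), with the stricter filter (0.0362), with DESeq2 (0.0218) and without control replicate 192 (0.0298). The count was 383 without KO replicate 205 and 669 without 218 at 2 weeks, 403 without KO replicate 229, 534 without 223 and 543 without 228 at 8 weeks, and 2009 without control replicate 192.

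Both sexes were in every group, so the difference of the KO effect between sexes was tested. No gene of 18135 was called by edgeR, where 1560 had an unadjusted p under 0.05 and the smallest adjusted p was 0.28; DESeq2 was not run for this term. The 2-week libraries alone gave no call (530 at an unadjusted p under 0.05), and neither did the fit without KO replicate 223 (1000). Each group held 1 male at 8 weeks, and in simulation 26.9% of 2-fold differences between sexes were recovered. By smallest p, the differences, male minus female, were of Pgpep1l (-1.53), Myh11 (-0.95), Lmod1 (-0.77) and Ptprz1 (-1.28), none of which passed (edgeR adjusted p = 0.28). Averaged over contractile genes, log2 CPM relative to the mean of all libraries was -0.008 and -0.032 in KO females at 2 weeks. It was -0.51 and -0.48 in KO males and 0.36 to 0.64 in controls of that time. At 8 weeks it was -0.89 in the KO male and -0.69 to -0.52 in KO females. No gene list was tested for the sex term, so a difference between sexes is neither shown nor excluded.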

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

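The tests of a mislabelled sample, of both Itga8 alleles in replicate 222 and of a lower share of smooth muscle cells at either time were chosen after the result was seen, and the comparison of the control libraries in sets other than the labelled times came from the counts of splits. In 469 groups of 4 libraries, 36 had a library far from the other 3, where chance gives about 1 in 20, or 23.45. Control replicate 192 at 2 weeks and KO replicate 223 at 8 weeks accounted for 7 each and KO replicate 222 at 2 weeks for 4.

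In KO libraries at 2 weeks, replicate 222 was the lowest for Itga8 (4.85 CPM, others 871 to 1495), Mybpc2 (0.179, others 0.639 to 0.663) and Kpna2 (37.03, others 45.8 to 47.7), and the highest for Creb5 (104 CPM, others 60.1 to 65.4). Replicate 195 was the lowest for Ctgf (772 CPM, others 1416 to 1530.0) and had the most genes detected (24062, others 23328 to 23438), and replicate 218 was the lowest for Col4a6 (671 CPM, others 869 to 911). Among controls at 2 weeks, replicate 192 was the highest for Myl9 (6688 CPM, others 3453 to 3633), Flna (19514, others 11330.0 to 12344), Notch2 (261, others 189 to 195) and Npr1 (581, others 364 to 386). It was the lowest for Tpm4 (152 CPM, others 225 to 236), Cx3cr1 (5.94, others 9.84 to 10.4) and Vcan (70.5, others 108 to 116). Replicate 202 was the lowest for Lepr (14.6 CPM, others 18.6 to 19.3), Emcn (5.44, others 10.1 to 10.4) and Lama3 (6.38, others 7.37 to 7.46), and replicate 200 was the highest for Spp1 (1.34 CPM, others 0.929 to 0.98).

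In KO libraries at 8 weeks, replicate 223, the male of the group, was the highest for Yap1 (96.6 CPM, others 87.2 to 87.6), Cdk1 (7.31, others 4.72 to 4.95), Sele (17.5, others 11.6 to 12.4), Csf3r (12.8, others 4.08 to 4.71) and Fmod (1033, others 751 to 777). It was the lowest for Myh11 (1059 CPM, others 2131 to 2240.5) and Flna (2646, others 4550.5 to 4886). Replicate 230 was the lowest for Col10a1 (3.63 CPM, others 25.9 to 33.9), Nuak2 (5.20, others 9.22 to 10.1) and Retn (5.96, others 33.0 to 44.2), and replicate 228 for Fhl2 (69.6, others 128 to 141). Among controls at 8 weeks, replicate 226 was the highest for Col8a1 (29.1 CPM, others 7.28 to 9.18), Timp1 (28.4, others 12.8 to 14.3) and Apoe (681, others 569 to 582). Replicate 231 was the highest for Thbs1 (175 CPM, others 128 to 134) and the lowest for Cmklr1 (48.7, others 53.9 to 54.1), and replicate 236 was the lowest for Vstm2b (38.0, others 43.5 to 44.0) and Ltbp2 (90.7, others 121 to 127).

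A KO effect that differed between 2 and 8 weeks was flagged for 19 genes. They came from the genes named for the interaction by smallest p and from those with opposite calls. Their passing the interaction test is thus no further evidence, and genes named for other comparisons were not checked here. The log2 change was 2.46 for Lama3, 1.97 for Cpxm2, 1.72 for Myo10, 1.55 for Cpz, 4.87 for Igfbp2, 2.71 for Pappa2, 3.399 for Notch3, 1.71 for Angpt2, 1.21 for Mrgpre, 1.00 for Spry1, 0.96 for Agap1, 1.73 for Rasa4, 2.81 for Cdkl1 and 1.51 for Daam2. It was -1.42 for Lancl3, -0.77 for Uhrf1bp1l, -1.09 for Kpna2, -1.37 for Creb5 and -0.79 for Usp13. Creb5 and Kpna2 were also among the genes for which replicate 222 stood apart.

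The near absence of Itga8 transcripts in KO replicate 222 was weighed first. A control placed in the KO group was argued against, since Yap1 in this library was at 76.65 CPM and the lowest control at 2 weeks held 167 CPM. Loss of reads over a wider region was argued against by 12 neighbouring genes within 1 Mb, whose median log2 ratio to the other 3 KO libraries was 0.045. An animal with the Cre driver on both Itga8 alleles remained open: Itga8 was at 0.118% of the control mean, but the number of Cre alleles is not given in the sources used here, so the value cannot decide for it.

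The lower contractile transcripts in KO were weighed next. A lower share of smooth muscle cells in which all other cells gained alike was argued against. The mean log2 fold change of 16 macrophage markers exceeded that of 15 endothelial markers by 0.763 at 2 weeks (permutation p = 0.00804). At 8 weeks it did so by 0.988 (permutation p = 0.00205). These permutations treat markers as independent, though markers of a cell type moved together (estimated correlation 0.613 and 0.455 at 2 weeks). With libraries as the units, the difference was 0.683 and 1.002 in log2 CPM (exact p = 0.0286 at each time, the lowest that 4 against 4 can give). At 2 weeks it was 0.439 without control replicate 192 (exact p = 0.0857) and 0.537 without KO replicate 218 (0.114), so its size there owed much to these libraries. At 8 weeks it was 0.836 to 1.261 without 1 library (exact p = 0.0571 whichever KO library was left out, 0.0286 for a control). KO and control values did not overlap in any of these. Across the 12 marker lists, mean log2 fold changes ran from 0.25 (endothelial) to 3.48 (neutrophil) at 2 weeks and from 0.357 (Schwann cell) to 2.48 (cardiac and skeletal muscle) at 8 weeks. The last rested on KO replicate 223, without which the median of that list was -0.42 (3.27 with it), and the next highest was 2.30 (T and NK cell). Macrophages, at 1.01 and 1.70, were not the highest. An unequal gain of other cells, macrophages among them, would also lower the share of smooth muscle cells and raise the markers unevenly. A lower share as the whole or a part of the cause is therefore not excluded. Scaling was argued against by medians of the contractile list of -0.62 at 2 weeks and -1.07 at 8 weeks without it. Macrophage influx stayed open as a contributor: none of the 16 macrophage markers was in another list, control aortas held all 16 at 1 CPM or more, and the most abundant, Lyz2, was at 532 CPM in KO and 228 CPM in controls at 8 weeks. Lower transcription of contractile genes in KO cells remains a hypothesis, and single-cell data, which would separate it from a change in cell types, were not analysed here.

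The last pattern was a split of the controls with replicates 192 (2 weeks) and 226 (8 weeks) exchanged, which called more genes than the labelled times. Replicates 198, 200, 202 and 226 against 192, 231, 234 and 236 gave 1157 genes in edgeR, against 13 for the labelled times, so the controls held a structure larger than that of time. On the second principal component 226 (21.2) lay with the controls at 2 weeks (10.9 to 26.8), but so did 192 (16.8), which stood alone on the third (-72.6). An exchange of 192 with 226 was argued against by Y-linked transcripts at 0% of the male mean in 192, although a wrong time label of another kind stays open. Clock genes cannot decide on time of day for these sets, since 3 of 12 separated them, where 18.1% of all genes at 1 CPM or more did. Replicate 192 by itself stood apart from the other controls for several of them. Dbp was at 57.7 CPM (other controls 5.13 to 30.7), Per1 at 97.3 (24.0 to 47.6) and Arntl at 32.2 (49.5 to 62.2). Npas2 in 192 (86.8 CPM) lay among the others (70.9 to 96.4). Time of day thus stays open for 192, which also stood apart in genes of other kinds. Gene length stays open: the slopes relative to the control mean did not overlap between the sets (0.0113 to 0.0307 against -0.0385, in 192, to -0.00581), which goes with this explanation, but their gap of 0.0171 was short of the 0.05 set before the test. No biological explanation was tested.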

How the results depend on the processing

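Fits without 2 or more libraries together, females alone and the list medians under other scalings were chosen after the data were seen. Of 231 named gene results, 219 called, 4157 of 4219 comparisons with an alternative kept direction and side of the threshold, 37 lost the call, 20 gained it and 5 changed sign. Most were named for a large change or a small p in these same data, so this does not describe calls in general. The sign changes were all of Itga8 in the interaction, which was not called: -0.35 without KO replicate 222, -0.02 without control replicate 198, -0.03 without KO replicate 230, -0.01 without control replicate 236 (up to 0.34, without KO replicate 195) and -0.14 without 222, 192 and 223 together. No called gene changed sign under any alternative run. No paired analysis was run, since the replicate numbers are those of single animals and the labels give no pairing between groups.

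With a minimum log2 fold change of 1, fewer genes passed by construction: 1274 at 2 weeks, 2261 at 8 weeks, 6 between control times, 414 between KO times and 907 in the overlap of both times. List tests with an estimated correlation called 0 lists at 2 weeks and 1 at 8 weeks with camera, where the preset correlation called 21 and 24. The interaction called 190 genes with sex as a covariate and 439 with DESeq2. Between control times 7 genes were called without scaling, 8 without a filter and 302 with DESeq2, and between KO times DESeq2 called 2014. The cause of these differences was not tested. DESeq2 made 20.8% to 23.5% false calls in simulation, a share that need not carry over to the real counts.

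Leaving out 1 library at a time gave 1546 to 2922 calls at 2 weeks and 4090 to 5682 at 8 weeks (2477 and 5296 with all libraries), 17 to 21 and 24 to 29 lists, 60 to 167 calls in the interaction (116), 4 to 351 between control times (13) and 383 to 2009 between KO times (1091). The 2-week count was lowest without KO replicate 218 (1546) and was 1628 without 222. The control time count of 351 came without control replicate 226, and the other libraries concerned are given with the report's counts. Without KO replicate 222 and control replicate 192 together 2313 genes were called at 2 weeks, and 12 of 85 named results lost the call. Without 195 and 192 together 3474 were called, and in females alone 4782 at 8 weeks. Without 222, 192 and 223 the interaction called 84, control times 9 and KO times 1222 genes. A single fit of all libraries called 3504 at 2 weeks and 5089 at 8 weeks. Beyond the list medians given in the report, those of uncalled lists that changed sign without 1 library were heritable aneurysm genes (0.02 at 2 weeks without control replicate 192, -0.02 and -0.003 at 8 weeks without KO replicate 230 and control replicate 231), cholesterol synthesis genes at 2 weeks (-0.10 without KO replicate 205) and oxidative phosphorylation genes at 2 weeks (-0.06 to -0.01 without KO replicates 195 or 218 or control replicates 198, 200 or 202). With 1 count worth 0.0225 to 0.0268 CPM, changes of genes near that level were beyond measurement.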

Other observations

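Genes of the circadian clock were looked at in KO aortas after their values in the controls had been seen. At 8 weeks Npas2 (-1.84; edgeR adjusted p = 0.000208), Arntl (-1.05; 0.00107), Cry1 (-0.80; 0.0122) and Clock (-0.42; 0.00837) were lower in KO, and Ciart (2.17; 0.00627), Dbp (2.02; 0.0011), Per3 (1.25; 0.00132), Tef (0.85; 0.000262) and Nr1d2 (0.70; 0.00149) were higher. Per1 (0.67; edgeR adjusted p = 0.102), Per2 (0.00) and Nr1d1 (0.24) did not pass. At 2 weeks Npas2 alone of the 12 passed (-0.97, edgeR adjusted p = 0.00711), and none of the 12 passed in the interaction. Levels at 2 weeks differed within groups. Arntl was at 50.8 and 53.8 CPM in KO replicates 195 and 205, and at 31.9 and 27.3 CPM in 218 and 222. It was at 32.2 CPM in control replicate 192 and at 49.8 to 62.2 CPM in the other controls of that time. The lack of other calls at 2 weeks thus does not show that these genes were unchanged. The time of day of sampling is not given in the sources used here.

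KO replicate 223 at 8 weeks held more transcripts of heart muscle genes than any other library: Myh6 was at 458 CPM (at most 19.0 CPM elsewhere), Actc1 at 257 CPM (at most 121), Tnnt2 at 205 CPM (at most 37.5) and Myl7 at 111.5 CPM (at most 5.42).

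Other splits of the same libraries into equal groups were counted for each comparison, as a planned test. For KO against control at 2 weeks, 1 of 35 splits, the real one, reached 2477 calls and the highest other gave 6. At 8 weeks it was again 1 of 35, with 5296 calls and a highest other of 1. Between KO times it was also 1 of 35 (1091 calls, highest other 9). These shares were under the one set before the test and the lowest that 35 splits can give, which argues against chance without excluding it. All other splits mixed the groups compared, which puts a real difference into the spread within groups and so leaves few calls. Chance was not excluded between control times, where 2 of 35 reached 13 and the highest other gave 1157. For the interaction 3 of 60 drawn splits reached 116 calls and the highest other gave 566, which does not exclude chance by the share set before the test, but these splits cannot decide. In the sex term 60 of 60 splits reached the real count of 0 genes in edgeR (1560 at an unadjusted p under 0.05), and the highest other gave 1. Any split reaches 0, so this count cannot decide. Both interaction splits with more calls than the real one (351 and 566) kept the KO libraries parted by time, as did another with 96, and so carried the change between KO times. The other 56 mixed the KO libraries, which removes that change, and gave 0 to 3 calls.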
